A study of Mus musculus with 4 samples.

How the data were processed

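Poly-A selected RNA of mouse tumor tissue was made into Illumina libraries, 1 for each of 4 groups, per the labels' protocols. The authors deposited 1 table of FPKM values (fragments scaled to gene length and library size) with 27878 genes, gene symbols, biotypes and positions. Trimmomatic, HISAT2, Cufflinks and HTSeq and the genome build mm10 are named in the submitters' processing notes, without roles. Their versions, the gene annotation and the strand setting are not given in the sources used here. No gene in the table had 0 in all 4 libraries. The table's 4 value columns were matched to the samples by name, and 0 columns stayed unused. Whether the RNA of a group came from 1 mouse or from several is not stated in the labels.

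The positions and lengths were checked against GENCODE M21 (mm10). Of the gene identifiers, 27809 were in that annotation, 99.2% of them with the same start and end. The FPKM value times the summed exon length was a whole multiple of 1 step per library (tolerance 0.02) for 98.6% of the values in each library, and for 27437 genes in all 4. The step gives the reads on genes per library, 16472029 to 17192432, and the reads behind each value. A value of 1 library can thus be given its counting error, but the spread between mice cannot be estimated. Ratios carry exact conditional (Clopper-Pearson) 95% intervals from these reads, and levels in the plots exact Poisson intervals. Sequencing reads after PCR are not independent molecules, so intervals and floors cover counting error only. A fold against 0 reads was computed against a floor of 3 reads in that library.

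Groups were taken from the sample labels. Differences were taken as log2(FPKM + 1), which understates the change of genes with low values. A gene counted as higher or lower when the difference was at least 1 in size and the higher value at least 1 FPKM. With 1 library per group no test was run and no p-value is given. The 5 comparisons between 2 libraries and the departure of the combination from the sum of single differences were computed, as fixed before the data were examined. Named genes are those with the 10 largest positive and 10 largest negative differences among genes with at least 5 FPKM in the higher library (5 and 5 for the combination against the single treatments and the sum). Gene models without a standard name, immunoglobulin and T cell receptor segments, microRNAs, pseudogenes and hemoglobin genes were left out of that ranking. The members of each gene list with the largest and smallest difference and the highest mean FPKM were named too. This ranking rule was written after the table had been opened, and a few further members and muscle genes were named after their values were seen.

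The 36 gene lists were also fixed before the data were examined. A list's median difference was compared with 10000 random lists of the same size drawn from 20 bins of mean expression, over members with at least 1 FPKM in 1 library. Lists with fewer than 4 such members were not summarized, which left out regulatory T cells (2 members), skin keratinocytes (3) and lung epithelium (2). Some genes stand in several lists, such as Cxcl10 and Il1b. Overlaps between comparisons that share the PBS library were set beside 100 simulations of unchanged groups. Alternatives were a pseudocount of 0.1, rescaling to TPM, median-of-ratios scaling, no filter on low values, a floor of 5 FPKM, a size of 1.5, unmatched random lists and lists of members with at least 5 FPKM. Settings without muscle, fat and erythroid markers, or without the 679 genes whose values followed the muscle list (Pearson correlation of at least 0.95 over the 4 libraries), were added after seeing the data.

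The calculation was tested on reads simulated for Tara and PBS at the real depths. Of 40 genes each, 36 with a ratio of 2.5 and 40 with a ratio of 4 passed the size rule, as did 29 with a ratio of 0.4 and 38 with a ratio of 0.25. The changed genes were drawn from genes with a mean above the floor of 1 FPKM, so these counts may not hold for genes near it. Among 27237 unchanged genes, many of them below 1 FPKM, 121 passed the size rule from counting error alone. In the real comparison of Tara with PBS, 476 of the 13654 genes with at least 1 FPKM in the higher library passed. The 2 shares thus have unlike bases. Of the 474 real genes with whole read numbers, 266 had a counting interval that left out a ratio of 1. Counting intervals left out a ratio of 1 for 4.75% of unchanged genes, and 4.5% of unchanged lists lay outside the central 95% of random lists. These unchanged lists were drawn at random from genes simulated independently, so that share checks the calculation only. Genes of 1 list that vary together between tumor pieces can leave the random range more often, without any effect of a treatment. Symbols were used as the table gives them. In it 25 symbols had turned into dates and 19 were repeated, and for a repeated symbol in a list the row with the higher mean was used. Reads of near-identical genes, such as Lyz1 and Lyz2, the granzymes Gzmd to Gzmg, the myosins Myh1, Myh2 and Myh4 and the globins, and of overlapping or antisense genes can be split by the counting, so their values are uncertain. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.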

Results

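Messenger RNA was sequenced from tumors of C57BL/6 mice, 6 to 8 weeks old, that had received Lewis lung carcinoma (LLC) cells, a mouse lung cancer line, by injection into the back. Treatment began 7 days after the cells were given. The PBS group received 0.2 ml of saline into the abdomen every 3 days, 6 times. The Tara group received taraxasterol, a plant triterpenoid, at 10 mg/kg on the same schedule. The DC vaccine group received a dendritic cell (DC) tumor vaccine into the tail vein every 7 days, 3 times. The combination group received both, the first vaccine dose 12 hours after the first taraxasterol dose. Each group had 1 library, so the data hold 4 libraries and no replicates. No difference between groups was tested, and "higher" and "lower" below compare single libraries. The libraries held 17192432 (PBS), 16786515 (Tara), 16948488 (DC vaccine) and 16472029 (combination) reads on genes, and between 12987 and 13175 genes reached 1 FPKM, the length-scaled unit of the table. Among genes with whole read numbers, Eef1a1 had the most reads in all 4, with 1.29% to 1.61% of the reads. Counts of genes below refer to a log2(FPKM + 1) difference of at least 1 in size with at least 1 FPKM in the higher library. Ratios are ratios of FPKM with 95% counting intervals, which cover counting error only and not the difference between mice.

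The effect of the drug alone was addressed by comparing the Tara library with the PBS library. Type I collagen, transcripts of the neutrophil list and interferon-induced transcripts were lower in the Tara library, and a small set of macrophage genes and the cholesterol synthesis pathway were higher. Col1a1 (ENSMUSG00000001506, mm10 chromosome 11, 94936224 to 94953042), which encodes a chain of type I collagen, had 78.3 FPKM in PBS and 4.74 FPKM in Tara, a ratio of 0.0605 (0.0553 to 0.0661). S100a9 (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), a calcium-binding protein abundant in neutrophils, had 35.8 and 3.20 FPKM, a ratio of 0.0893 (0.0584 to 0.132). Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), an Fc receptor-like gene of macrophages and microglia, had 3.02 FPKM in PBS and 21.2 FPKM in Tara, a ratio of 7.03 (5.81 to 8.58).

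Among 13654 genes compared, 200 were higher and 276 lower in Tara, 40 and 157 of them protein-coding. Of the 474 of these with whole read numbers, 81 higher and 185 lower genes had a counting interval that left out a ratio of 1. Besides Col1a1 and S100a9, large negative differences were in Col1a2 (log2 difference -3.56), the matrix-degrading protease Ctsk (-3.22), S100a8 (-3.05), the alarmin cytokine Il33 (-2.69), the Wnt modulator Sfrp2 (-2.69), the granzyme Gzmg (-2.65) and Cpxm1 (-2.57). The largest positive differences in protein-coding genes, after Fcrls, were in Lyz1 (2.35), a lysozyme, Mgl2 (1.88), a macrophage lectin, the glutathione transferase Gstt1 (1.36), the ion channel Trpa1 (1.22) and Tmem176b (1.11). The other 4 places among the 10 were taken by the small RNAs Snora41, Scarna17, Snora47 and Snord71, each with 14 reads or fewer in both libraries.

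The gene lists placed these genes in groups. All 12 measured genes of the neutrophil list were lower in Tara, 8 of them by 1 or more, with a median of -1.38. Ly6g, a neutrophil surface marker on that list, had only 3 reads in PBS and 2 in Tara, too few to tell whether neutrophil number changed. All 16 measured genes of the interferon-gamma response were lower (median -0.85), 5 of them by 1 or more. The guanylate-binding protein Gbp2 had 131.8 FPKM in PBS and 41.9 in Tara, and the chemokine Cxcl10 had 34.2 and 18.4. Of the 20 interferon-stimulated genes, 18 were lower, with a median of -0.41. The macrophage genes of classical activation had a median of -0.69, with Nos2, which makes nitric oxide, at 6.43 and 0.859 FPKM. The lymphocyte-attracting chemokines also had a median of -0.69, and Ccl4 had 12.9 FPKM in PBS against 4.51 in Tara. In the list of alternative activation the members went both ways (6 above and 6 below 0): Arg1, which breaks down arginine, had 83.2 FPKM in PBS and 18.5 in Tara, while Mgl2 was higher. The fibroblast and matrix list was lower in 15 of 16 genes (median -0.84), although Col3a1, its most abundant member, had 261 and 227 FPKM.

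The list of cytotoxic lymphocytes was lower in 10 of 13 genes (median -0.45), with Prf1 (perforin) at 12.4 FPKM in PBS and 4.47 in Tara. Inhibitory checkpoint genes were lower in 10 of 11 (median -0.50), and T cell genes had a median of -0.09 within the central 95% of random lists. Hypoxia and glycolysis genes were lower in 19 of 20 (median -0.51), with the vasoactive peptide Adm at 59.0 and 16.2 FPKM. NF-kappaB targets had a median of -0.48, and heat shock and immediate-early genes a median of -0.38. All 18 cholesterol synthesis genes were higher in Tara, with a median of 0.71 and none by 1 or more. Cyp51, an enzyme of the pathway, had 19.5 and 38.9 FPKM. MHC class II genes were higher in 8 of 9 (median 0.44), with H2-Eb1 at 52.2 and 99.4 FPKM. MHC class I genes were lower in 13 of 15 (median -0.19). The macrophage and monocyte list was higher in 10 of 16 (median 0.29), dendritic cell genes in 8 of 11 (0.35) and genes of mast cells and eosinophils in 4 of 6 (0.80), with Gata2 lower at 1.44 and 0.839 FPKM. Proliferation genes (median 0.09) and apoptosis and p53 targets (0.00) lay within the central 95% of random lists. NRF2 targets (median 0.11) lay within the random range too, and among them Hmox1 (heme oxygenase) had 231.8 FPKM in PBS and 42.2 in Tara.

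Transcripts of other tissues differed between the same libraries. All 19 skeletal muscle genes were lower in Tara (median -1.62), and Acta1, the skeletal actin, had 79.4 and 18.1 FPKM. All 6 erythroid genes were lower (median -1.82), with the beta-globin Hbb-bs at 157.3 and 34.4 FPKM. Adipocyte genes had a median of 0.00, and endothelial genes were lower in all 14 (median -0.20). Each median named here was outside the central 95% of 10000 random lists matched on expression, except where stated and for adipocyte genes. Counts of this comparison and of the others depended on the pseudocount, the scale and the floor. In place of 476 genes, 926 differed between Tara and PBS with a pseudocount of 0.1, 1566 after rescaling to TPM and 162 with a floor of 5 FPKM.

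**Figure D1:**
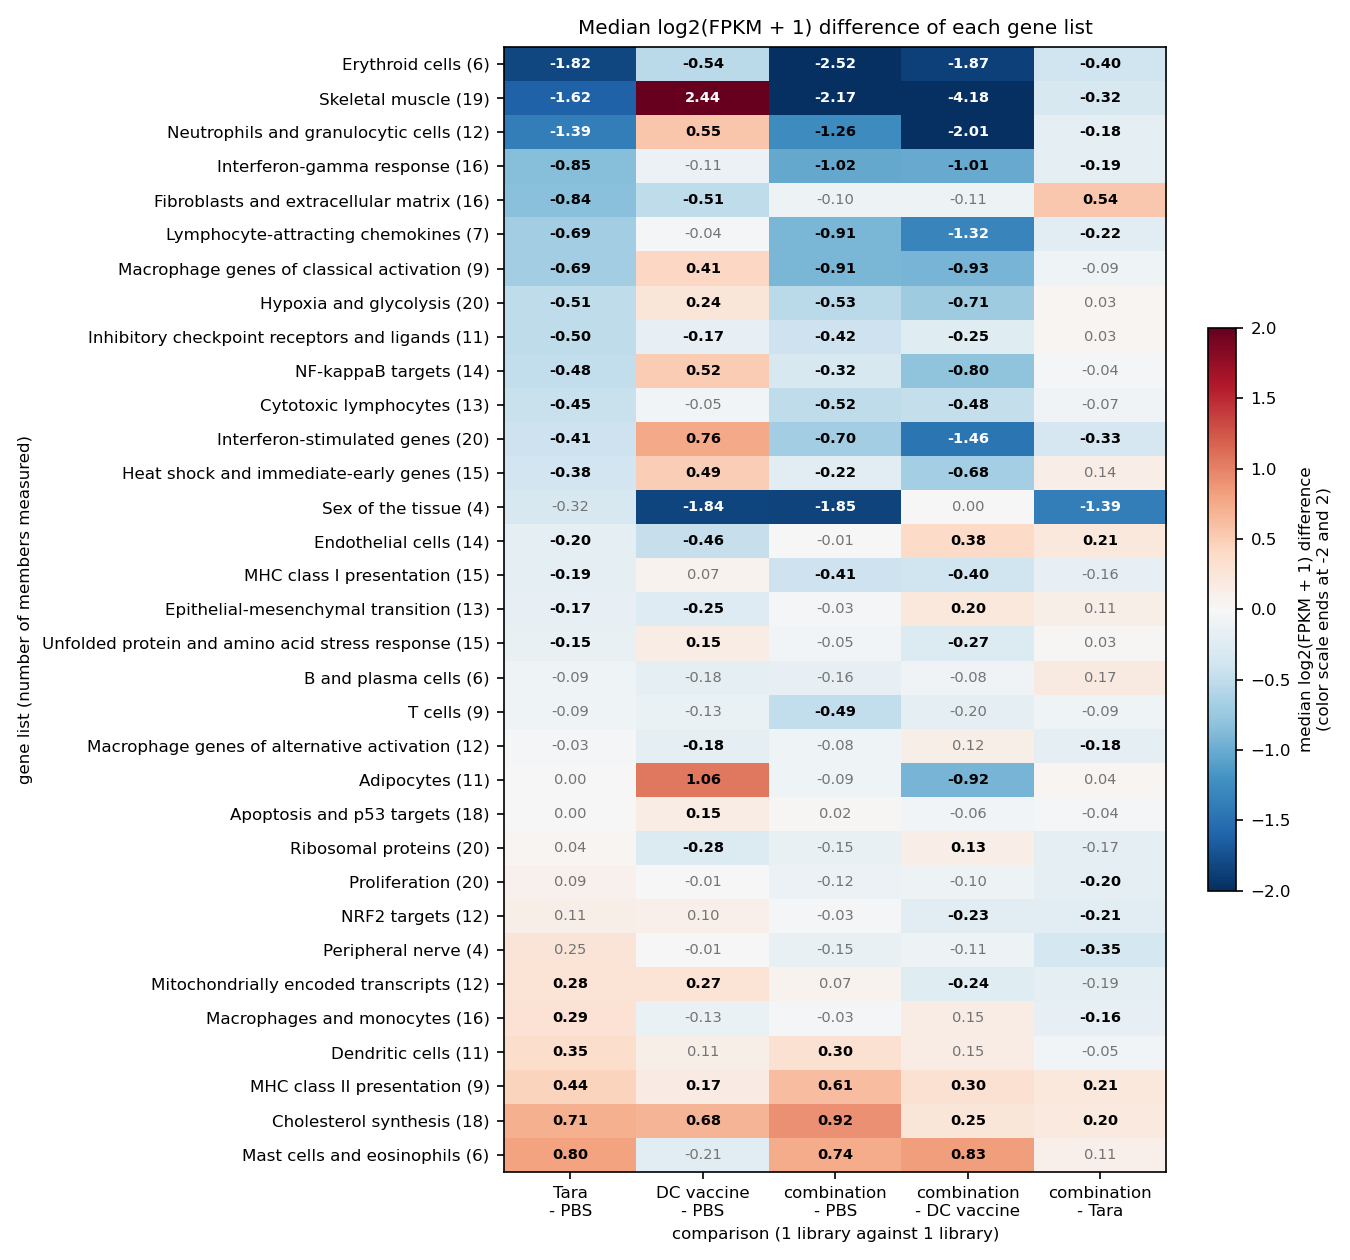
Median log2(FPKM + 1) difference of each gene list (rows, with the number of measured members) in 5 comparisons of 1 library with another (columns), with red for higher and blue for lower in the first named library. Bold values lie outside the central 95% of 10000 random lists matched on expression; the interferon-gamma list, for example, had -0.85, -0.11, -1.02, -1.01 and -0.19 from left to right.

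The vaccine alone was examined in the DC vaccine library against PBS. Muscle and fat transcripts, interferon-stimulated genes, neutrophil genes and macrophage genes of classical activation were higher in the DC vaccine library, and Y-linked genes, Ctsk and Esm1 were lower. Atp2a1 (ENSMUSG00000030730, chromosome 7, 126445858 to 126463108), the calcium pump of fast muscle, had 10.6 FPKM in PBS and 91.4 in the DC vaccine library, a ratio of 8.63 (7.95 to 9.39). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, had 10.8 and 37.0 FPKM, a ratio of 3.44 (3.05 to 3.88). Eif2s3y (ENSMUSG00000069049, chromosome Y, 1010543 to 1028847) had 437 reads in PBS and 0 in the DC vaccine library, so it was at least 143.6-fold higher in PBS when 3 reads are set as the floor.

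Of 13738 genes compared, 360 were higher and 174 lower in the DC vaccine library, 198 and 57 of them protein-coding. Counting intervals left out a ratio of 1 for 242 of the higher and 90 of the lower genes. The largest positive differences were in Cfd (3.48), the complement factor made by fat cells, Ly6g (3.16), a neutrophil surface marker, Pdk4 (3.06), Retnla (3.05), the muscle genes Atp2a1 (3.00), Mb (2.95), Myh1 (2.84), Ckm (2.83), Actn3 (2.70) and Pvalb (2.67). Ly6g had 3 reads in PBS and 153 in the DC vaccine library, a ratio of 51.7 (17.4 to 253.6), and Retnla had 1 and 82 reads, a ratio of 83.2 (14.5 to 3325). The largest negative differences were in Eif2s3y (-2.83), Ddx3y (-2.60), Ctsk (-2.52), the endothelial gene Esm1 (-2.33), Cpxm1 (-1.92), the keratin Krt18 (-1.75), the protease Mmp9 (-1.69) and Col1a1 (-1.66), and in the small RNAs Snord49a and Snord58b with 19 reads or fewer.

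All 20 interferon-stimulated genes were higher in the DC vaccine library (median 0.76), 4 of them by 1 or more. Mx1, an antiviral GTPase, had 4.73 FPKM in PBS and 14.4 in the DC vaccine library. The interferon-gamma list had a median of -0.11, with 5 genes above and 11 below 0, within the central 95% of random lists. Neutrophil genes were higher in 9 of 12 (median 0.55) with S100a9 at 35.8 and 49.6 FPKM, while Mmp9 had 13.8 and 3.58. Macrophage genes of classical activation were higher in 8 of 9 (median 0.41), and NF-kappaB targets in 12 of 14 (0.52). Macrophage and monocyte genes were lower in 13 of 16 (median -0.13, within the random range), and genes of alternative activation in 7 of 12 (median -0.18), a direction that depended on members below 5 FPKM. Heat shock and immediate-early genes had a median of 0.49, with the transcription factor Junb at 52.9 and 112.4 FPKM. All 18 cholesterol synthesis genes were higher (median 0.68), with Idi1 at 9.46 and 19.1 FPKM. Hypoxia genes had a median of 0.24. Fibroblast and matrix genes were lower in 11 of 16 (median -0.51), although Dcn (decorin) had 19.3 and 38.1 FPKM. Endothelial genes were lower in 12 of 14 (median -0.46), with Cdh5 at 17.3 and 9.63 FPKM. All 20 ribosomal protein genes were lower (median -0.28).

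Inhibitory checkpoint genes had a median of -0.17 and MHC class II genes one of 0.17, both outside the central 95% of random lists, and Pdcd1, which encodes PD-1, had 2.95 and 1.53 FPKM. T cell genes (-0.13), cytotoxic genes (-0.05), B and plasma cell genes (-0.18) and lymphocyte-attracting chemokines (-0.04) had medians within the central 95% of random lists, and the B cell and chemokine medians turned positive after rescaling to TPM. Among members, Gzma had 3.01 FPKM in PBS and 7.39 in the DC vaccine library, Ighm had 3.67 and 10.2, and Cd8b1 had 3.53 and 1.79. Dendritic cell genes had a median of 0.11 within the random range, with the chemokine Ccl22 at 0.5003 and 3.86 FPKM. All 19 muscle genes were higher (median 2.44), 18 of them by 1 or more, and adipocyte genes were higher in 8 of 11 (median 1.06). Erythroid genes had a median of -0.54. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 1301 reads in PBS and 2 in the DC vaccine library, while Xist, expressed from an inactive X chromosome, had 5.12 and 4.89 FPKM.

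The combination of drug and vaccine was compared with PBS next. As in Tara, genes of the neutrophil list and interferon-gamma response genes were lower than in PBS, and Fcrls was higher. Type I collagen was lower, and MHC class II and cholesterol synthesis genes were higher, as in both the Tara and the DC vaccine library. In the DC vaccine library Col1a1 had 24.0 FPKM and MHC class II genes had a median of 0.17 against PBS. S100a9 had 321 reads in PBS and 8 in the combination, a ratio of 0.0260 (0.0111 to 0.0519). Col1a1 had 78.3 and 5.75 FPKM, a ratio of 0.0735 (0.0677 to 0.0797), and Fcrls had 3.02 and 16.3 FPKM, a ratio of 5.41 (4.45 to 6.63). Genes that were also higher in the DC vaccine library included Nos1 (ENSMUSG00000029361, chromosome 5, 117781032 to 117958840), the neuronal nitric oxide synthase, with 2.41 FPKM in PBS and 9.72 in the combination.

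Of 13646 genes, 210 were higher and 298 lower in the combination, 56 and 178 of them protein-coding. After rescaling to TPM 847 were higher and 819 lower, so the excess of lower genes depended on the scale. Counting intervals left out a ratio of 1 for 100 of the higher and 215 of the lower genes. The largest positive differences were in Fcrls (2.11), Enpp2 (2.00), which makes lysophosphatidic acid, Nos1 (1.65), Lyz1 (1.64), Mgl2 (1.51), the neurotrophic factor Artn (1.43), Idh1 (1.40), an isocitrate dehydrogenase, and Fbn1 (1.32), a microfibril protein, besides Snora47 and Snord71 with 14 reads or fewer. The largest negative differences were in S100a9 (-4.25), Col1a1 (-3.55), Col1a2 (-3.33), Ctsk (-3.18), the platelet chemokine Ppbp (-2.91), Eif2s3y (-2.83), S100a8 (-2.81), Il33 (-2.73), Acta1 (-2.67) and the extracellular glutathione peroxidase Gpx3 (-2.66).

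All 16 interferon-gamma response genes were lower in the combination (median -1.02), 8 of them by 1 or more, with Gbp2 at 131.8 and 34.8 FPKM. All 20 interferon-stimulated genes were lower (median -0.70), 4 of them by 1 or more. Neutrophil genes were lower in 11 of 12 (median -1.26) and classical activation genes in 7 of 9 (median -0.91). The neutrophil marker Ly6g had 3 reads in PBS and 5 in the combination. Cytotoxic genes were lower in 12 of 13 (median -0.52), with Gzmb at 25.2 and 10.95 FPKM and Prf1 at 12.4 and 4.30. T cell genes were lower in 7 of 9 (median -0.49), and Cd3d had 1.89 and 0.669 FPKM. A further list of pan-leukocyte genes such as Ptprc had 2 of 16 members above 0 (median -0.19). Fewer leukocytes can thus have added to the lower lymphocyte genes. The checkpoint list was lower in 9 of 11 (median -0.42), and Cd274, which encodes PD-L1, had 13.2 and 5.08 FPKM. Lymphocyte-attracting chemokines had a median of -0.91 with Ccl3 at 13.3 and 2.93 FPKM. MHC class I genes were lower in 14 of 15 (median -0.41) and MHC class II genes higher in 7 of 9 (median 0.61), with H2-Eb1 at 52.2 and 125.9 FPKM. Dendritic cell genes had a median of 0.30, and Ccr7, a homing receptor of mature dendritic cells and of T cells, had 2.44 and 6.23 FPKM. All 18 cholesterol synthesis genes were higher (median 0.92), 5 of them by 1 or more. Their medians against PBS were similar in Tara (0.71) and the DC vaccine library (0.68). Without the PBS library they were smaller, 0.25 for combination minus DC vaccine and 0.20 for combination minus Tara. Part of the rise can thus come from the shared PBS library.

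Hypoxia genes were lower in 19 of 20 (median -0.53), with Pgk1 at 663 and 384 FPKM. Macrophage genes of alternative activation had a median of -0.08 within the random range. Arg1 had 83.2 FPKM in PBS and 14.3 in the combination, and Retnla had 1 and 37 reads, a ratio of 38.6 (6.51 to 1566). The fibroblast list had a median of -0.10 within the random range, with Pdgfra at 19.98 and 32.6 FPKM. Proliferation genes (median -0.12), apoptosis and p53 targets (0.02) and NRF2 targets (-0.03) lay within the random range too. Mast cell genes were higher in 5 of 6 (median 0.74), with Cpa3 at 1.42 and 3.88 FPKM. All 19 muscle genes (median -2.17) and all 6 erythroid genes (-2.52) were lower. The 4 Y-linked genes had 0 reads in the combination.

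**Figure D2:**
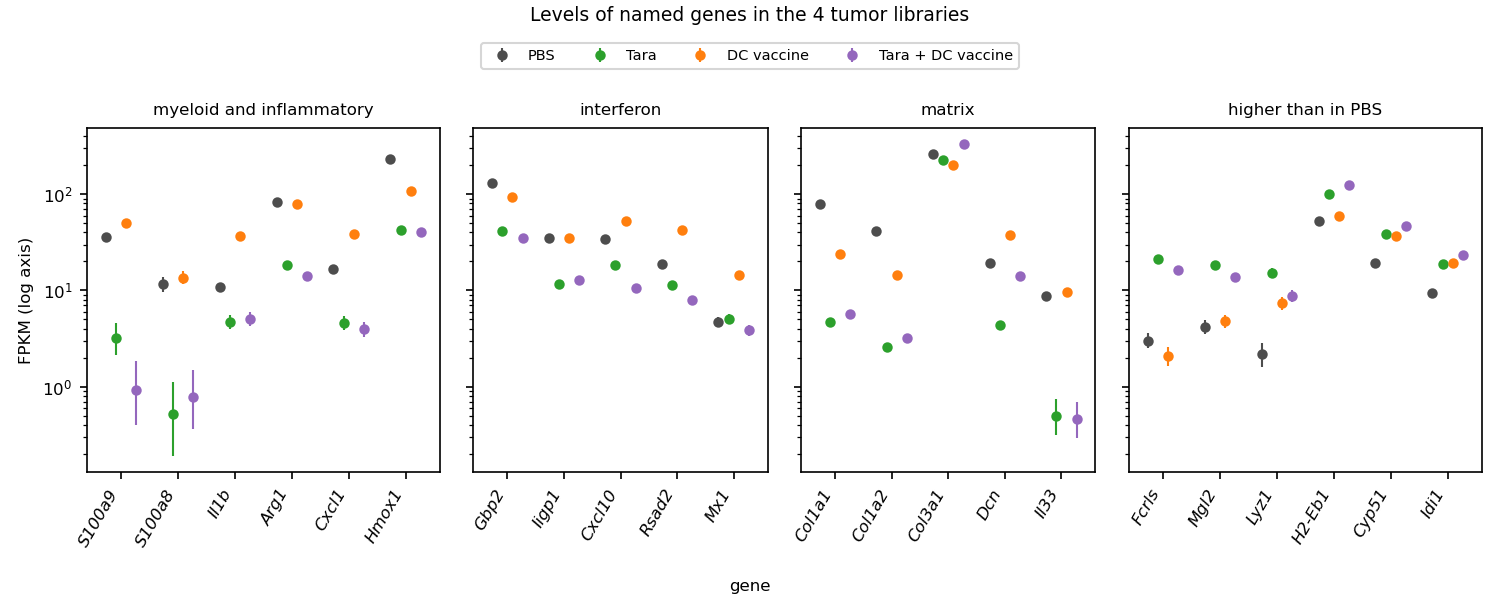
FPKM (log axis) of named genes in each of the 4 libraries (colors), with exact Poisson 95% intervals of the reads as bars, which cover counting error only. Arg1, for example, had 83.2 FPKM in PBS, 18.5 in Tara, 79.2 in the DC vaccine library and 14.3 in the combination.

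What the drug added to the vaccine was read from the combination against the DC vaccine library, a pair that shares no library with Tara against PBS. Muscle, granulocyte, interferon and inflammatory transcripts were lower in the combination, and Fcrls, Krt18 and endothelial genes were higher. Atp2a1 had 91.4 FPKM in the DC vaccine library and 1.03 in the combination, a ratio of 0.0113 (0.00857 to 0.0146). S100a9 had 49.6 and 0.930 FPKM, a ratio of 0.0187 (0.00804 to 0.0373). Fcrls had 2.07 and 16.3 FPKM, a ratio of 7.87 (6.24 to 10.0), and Krt18 (ENSMUSG00000023043, chromosome 15, 102028180 to 102032027) had 9.16 and 51.8 FPKM, a ratio of 5.66 (4.91 to 6.56).

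This pair had the most genes past the size rule of the comparisons between 2 libraries, with 211 higher and 511 lower of 13830. Counting intervals left out a ratio of 1 for 102 and 407 of them. After Fcrls and Krt18 the largest positive differences were in the membrane peptidase Mme (2.06), the clock gene Per1 (1.81) and Vamp8 (1.73). The 5 largest negative differences were all in muscle genes, Atp2a1 (-5.51), Pvalb (-5.27), Acta1 (-5.09), Ckm (-5.05) and Myh4 (-4.92), and the muscle list had a median of -4.18. Interferon-stimulated genes were lower in 20 of 20 (median -1.46), 17 of them by 1 or more, with Rsad2 at 42.9 and 7.91 FPKM. Interferon-gamma genes were lower in 16 of 16 (median -1.01) and neutrophil genes in 11 of 12 (median -2.01). Classical activation genes were lower in 9 of 9 (median -0.93), with Il1b at 37.0 and 5.06 FPKM. Among NF-kappaB targets, 13 of 14 were lower (median -0.80), and the neutrophil chemokine Cxcl1 had 38.8 and 3.98 FPKM. Cytotoxic genes had a median of -0.48, checkpoint genes one of -0.25 and chemokines one of -1.32. Hypoxia genes were lower in 19 of 20 (median -0.71). Endothelial genes were higher in 12 of 14 (median 0.38), mast cell genes in 6 of 6 (0.83), MHC class II genes in 7 of 9 (0.30) and cholesterol synthesis genes in 17 of 18 (0.25). Adipocyte genes had a median of -0.92 and erythroid genes one of -1.87.

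What the vaccine added to the drug was read from the combination against the Tara library. Fewer genes passed the size rule here, 174 higher and 180 lower of 13616 (705 and 615 with TPM), and counting intervals left out a ratio of 1 for 65 and 76 of them. Matrix genes were higher in the combination: 15 of 16 fibroblast and matrix genes had a positive difference (median 0.54), and Dcn had 4.37 FPKM in Tara and 14.0 in the combination. Nos1 had 1.54 and 9.72 FPKM, a ratio of 6.32 (5.57 to 7.18). The largest positive differences after Nos1 (2.08) were in the epithelial galectin Lgals7 (1.99), the protease Mmp3 (1.87) and Vamp8 (1.55), and in the ribosomal RNA gene n-R5s197 with 2 and 10 reads. Ndn (-2.48), an imprinted gene, had 11.1 FPKM in Tara and 1.17 in the combination, a ratio of 0.105 (0.0812 to 0.134). Further negative differences were in the netrin Ntn4 (-1.86) and the transmembrane glycoprotein Gpnmb (-1.51), and in Scarna17 and Snord73a with 19 reads or fewer.

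Gene lists differed less between this pair. Interferon-stimulated genes were lower in 18 of 20 (median -0.33) and interferon-gamma genes in 13 of 16 (median -0.19), with Cxcl10 at 18.4 and 10.6 FPKM. Proliferation genes were lower in 19 of 20 (median -0.20), NRF2 targets in 10 of 12 (-0.21) and macrophage genes in 11 of 16 (-0.16), with Apoe, the lipid carrier, at 430 and 202 FPKM. Endothelial genes were higher in 13 of 14 (0.21), cholesterol synthesis genes in 17 of 18 (0.20) and MHC class II genes in 7 of 9 (0.21). Within the stress response list, whose median of 0.03 lay in the random range, Ddit4 had 24.8 and 68.6 FPKM. T cell (-0.09), cytotoxic (-0.07) and checkpoint genes (0.03) lay within the random range. Muscle genes had a median of -0.32 and erythroid genes one of -0.40.

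**Figure D3:**
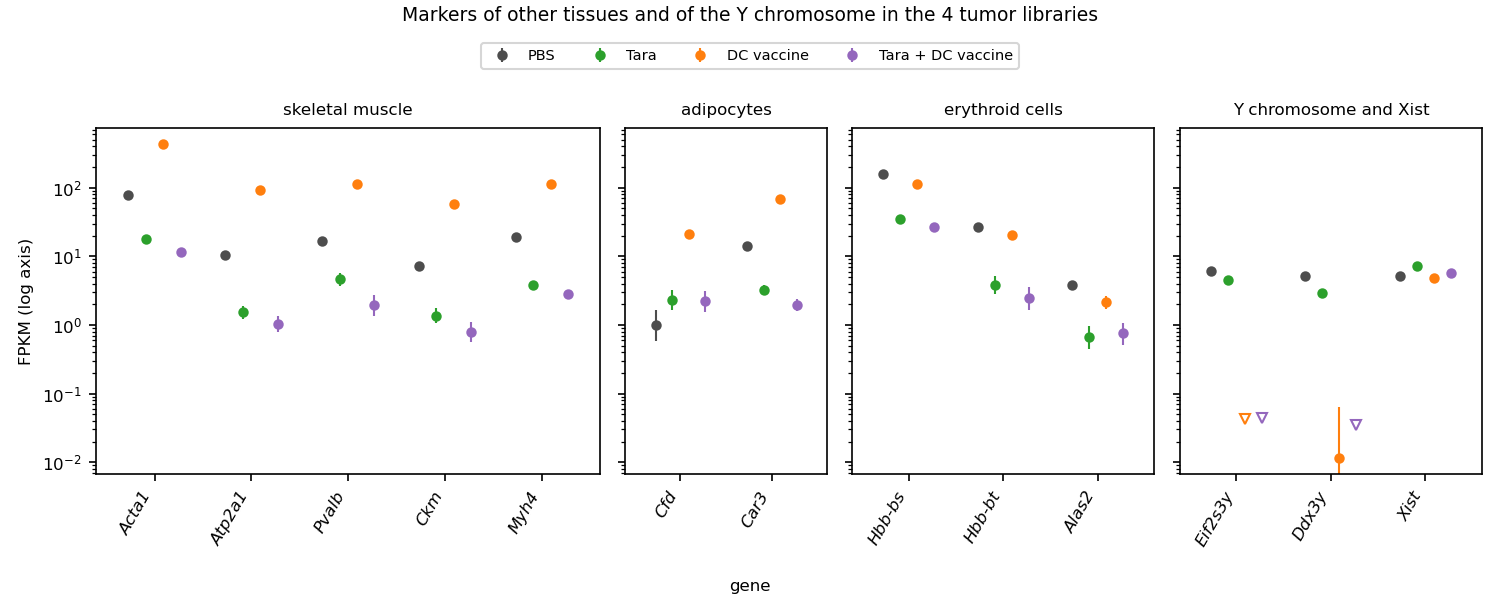
FPKM (log axis) of markers of muscle, fat and erythroid cells and of Y-linked genes and Xist in each of the 4 libraries (colors), with exact Poisson 95% intervals of the reads as bars, and open triangles at the level of 3 reads where a library had 0 reads. Acta1 had 79.4 FPKM in PBS, 18.1 in Tara, 429.6 in the DC vaccine library and 11.7 in the combination.

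Whether the combination equaled the sum of the single differences was computed as combination minus Tara minus DC vaccine plus PBS on the log2(FPKM + 1) scale. Of 14374 genes, 352 lay above and 552 below the sum by 1 or more, and no interval was computed for these values. Interferon-stimulated genes lay below the sum in 20 of 20 (median -1.08), and cholesterol synthesis genes in 17 of 18 (median -0.48). Fibroblast and matrix genes lay above it in 16 of 16 (median 1.03) and endothelial genes in 14 of 14 (median 0.62). The PBS value enters this measure with a plus sign. A list that is low in the PBS library alone thus falls below the sum, and one that is high there alone lies above it. Part of these departures can therefore come from the PBS library. Interferon-gamma genes had a median of -0.04 within the random range. Single genes far above the sum were Krt18 (3.06), Esm1 (2.81), Ctsk (2.56) and Per1 (2.41), and Snord58b with 11 reads or fewer. Ctsk had 22.62 FPKM in PBS, 1.537 in Tara, 3.122 in the DC vaccine library and 1.606 in the combination. Esm1 had 14.95, 2.017, 2.167 and 3.213 FPKM in the same order. For Ctsk and Esm1 the sum lies below the lowest value the scale allows, so any combination value would exceed it. Neither gene was higher in the combination than in PBS, unlike Krt18 and Per1. Genes far below the sum were Pvalb (-3.59), Cfd (-3.52), Myh1 (-3.40), Atp2a1 (-3.31) and Ckm (-3.23), and the muscle list had a median of -2.88.

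The treated libraries were each compared with the same PBS library, so shared genes can arise by chance. Tara and the combination shared 54 higher and 194 lower genes. Among the 13301 genes compared in both, Tara had 105 higher and 276 lower genes and the combination 129 and 298, and independent lists of these sizes would share 1.0 and 6.2. Simulated unchanged groups that used the same PBS library shared a mean of 47.4 higher genes (at most 68 in 100 simulations) and 61.2 lower genes (at most 91). The DC vaccine and the combination shared 60 higher and 86 lower genes, against 2.0 and 3.9 for independent lists (205 and 127 higher, 174 and 298 lower genes compared in both) and means of 48.2 and 60.7 in the simulations (at most 67 and 87). Tara and the DC vaccine shared 48 and 81, against 1.5 and 3.6 for independent lists (100 and 201 higher, 276 and 174 lower genes) and means of 47.2 and 62.2 in the simulations (at most 73 and 83). Of these overlaps, only the 194 lower genes of Tara and the combination exceeded the simulated maximum. The simulations drew each gene independently, but genes of 1 tissue vary together, so that maximum can be too low. All 19 muscle and all 6 erythroid genes, for example, were lower in both comparisons. The excess therefore does not separate the drug from tissue content of the PBS library. The covariance of the log2 differences was 0.0974 for Tara and the combination, 0.0455 for the DC vaccine and the combination, and 0.0388 for Tara and the DC vaccine, beside 0.0648, 0.0648 and 0.0650 in the simulations. The simulated spread came from the departures from the sum of single differences, so it holds any true departure too, and part of each overlap can come from the shared PBS library.

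Pairs without a shared library avoid that link. Across 14374 genes, which are not independent replicates, the difference Tara minus PBS had a Pearson correlation of 0.306 and a Spearman correlation of 0.221 with the difference combination minus DC vaccine. In both pairs 21 genes were higher by 1 or more and 105 were lower, and 29 went opposite ways (99, 287 and 134 with a pseudocount of 0.1). For the vaccine, the difference DC vaccine minus PBS had a Pearson correlation of 0.0472 and a Spearman correlation of 0.0714 with combination minus Tara, with 26 genes higher, 11 lower and 29 opposite (96, 77 and 144 with a pseudocount of 0.1). These 2 relations were added after the data had been seen.

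**Figure D4:**
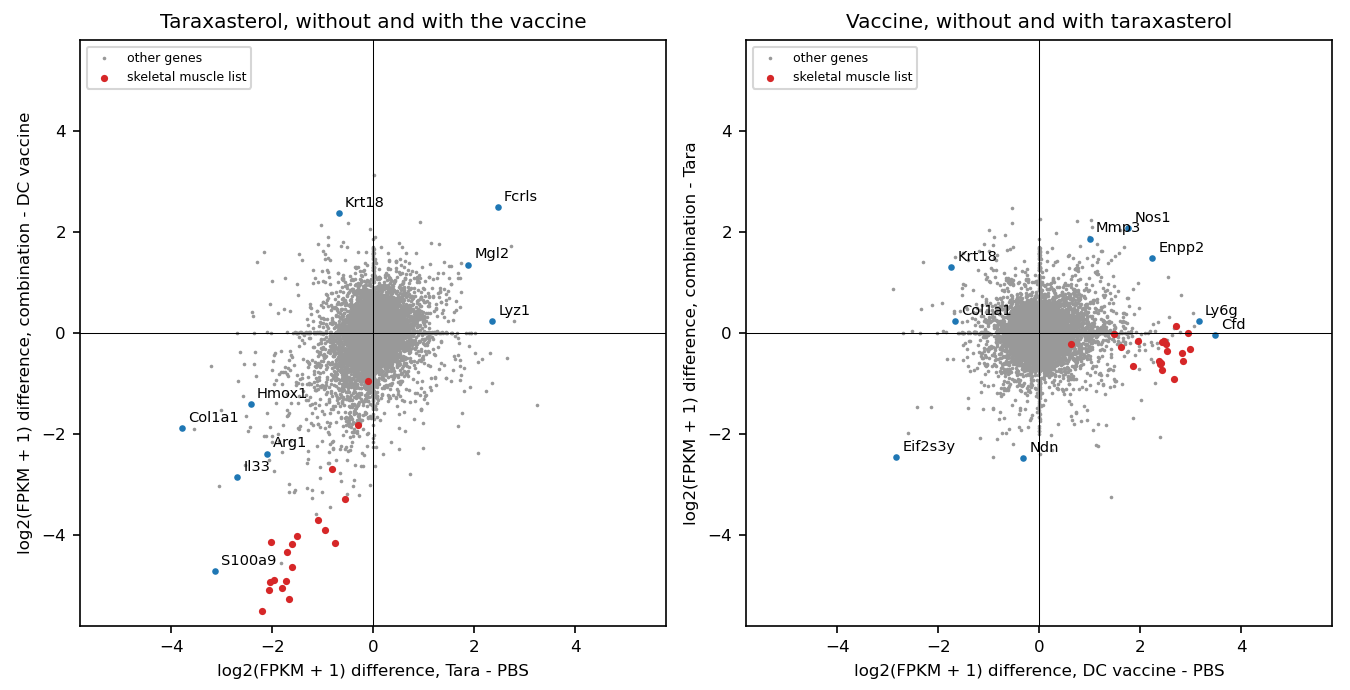
Log2(FPKM + 1) differences of 14374 genes (points), for taraxasterol without (x axis) and with the vaccine (y axis) on the left, and for the vaccine without (x axis) and with taraxasterol (y axis) on the right, with skeletal muscle genes in red and named genes in blue. Fcrls lay at 2.47 and 2.49 and S100a9 at -3.13 and -4.71 in the left plot.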

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

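The tests in this part that use PBS alone being high, muscle and fat, blood, and Xist were chosen after the results had been seen; the second muscle list, the early myogenic genes and the pan-leukocyte genes were set before their values were looked at. With 1 library per group no library was checked for standing apart from its group. A gene list was picked out when its median for the same treatment went opposite ways with and without the other treatment, by at least 0.25 each way. That rule was written after the table had been opened, and these differences were not tested.

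Skeletal muscle genes went with the vaccine in opposite directions: the median was 2.44 for DC vaccine minus PBS and -0.32 for combination minus Tara, a difference of -2.75. A second list of mature muscle genes, such as Ttn and Neb, was higher in the DC vaccine library than in PBS in 23 of 23 members, with a median of 1.37. Early myogenic genes had a median of 0.0637 over 7 measured genes, 5 of them near 0 FPKM, and of 0.461 over the 2 that reached 1 FPKM, Myh3 and Myf6 (0.276 FPKM in PBS and 1.36 in the DC vaccine library). The near absence of Myod1, Myog and Myf5 speaks for muscle tissue in the sampled piece. Myf6 was higher along with the mature muscle genes, so it does not separate muscle tissue from a muscle program in tumor cells. With so few genes measured, such a program is not excluded. No biological explanation from the treatments was tested, and with 1 library the vaccine and the piece of tissue cannot be separated.

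Interferon-stimulated genes also went opposite ways with the vaccine, with a median of 0.76 without and -0.33 with taraxasterol, a difference of -1.09. Against PBS their medians were 0.76 (DC vaccine), -0.41 (Tara) and -0.70 (combination). The muscle list ranked the libraries in the same order (2.44, -1.62 and -2.17), so the treatments and the tissue content of the pieces cannot be separated here. Fibroblast and matrix genes had -0.51 without and 0.54 with taraxasterol, a difference of 1.04.

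Interferon-gamma response genes were lower in both libraries with taraxasterol. A high PBS library alone would leave the pair without it near 0, but combination minus DC vaccine had a median of -1.01, with 16 of 16 genes lower. Fewer immune cells overall would lower pan-leukocyte genes such as Ptprc and Coro1a in both pairs, but their median was 0.038 for Tara minus PBS and -0.261 for combination minus DC vaccine, so fewer leukocytes do not account for the first pair but can have added to the second. If muscle and fat raised the list, it would be higher in the DC vaccine library, where its median was -0.11. Whether they raise these genes is not known, so this test cannot exclude them. The muscle list was lower in both pairs (-1.62 and -4.18). Blood in the piece stays open too, since the erythroid list was lower in both pairs, the smaller difference being -1.82. A lower interferon-gamma response under taraxasterol may be kept only as a hypothesis. Beside it stand blood, muscle and fat in the piece, and chance differences between mice. Fewer cells of 1 kind, such as cytotoxic lymphocytes (medians -0.45 and -0.48), remain possible too.

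Reads of the 4 Y-linked genes were 1301 in PBS, 841 in Tara, 2 in the DC vaccine library and 0 in the combination. If the mice differed in sex, Xist could be higher in the libraries without Y-linked reads, but the lowest Xist value there was 0.677 times the highest value in the others. Xist had 5.12, 7.21, 4.89 and 5.73 FPKM in PBS, Tara, DC vaccine and combination. The tumor line can add its own Xist and Y-linked reads, so mice of different sex, loss of the Y chromosome in tumor cells and a mix-up of libraries cannot be told apart here. Every comparison of a vaccine library with one without the vaccine also compares libraries without and with Y-linked reads.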

How the results depend on the processing

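The settings without muscle genes and all settings for correlations and for splits of the libraries were added after the data had been seen. With a pseudocount of 1 the size rule already requires 1 FPKM in the higher library. Dropping the filter on low values could therefore not change the 5 counts between 2 libraries, and the count against the sum went from 904 to 993. Median-of-ratios scaling and leaving out muscle, fat and erythroid markers kept each of the 6 counts of genes within 1.5 times its main value. Leaving out genes that followed the muscle list did so too, but that filter picks genes by the very difference counted, so it cannot separate muscle from treatment. It left 284 of the 511 lower genes of combination against DC vaccine, 69 of the 99 genes separated by taraxasterol, and 69 of the 105 genes lower in both pairs. Counts are given below in the order Tara, DC vaccine and combination against PBS, combination against DC vaccine, combination against Tara, and combination against the sum, for which the main counts were 476, 534, 508, 722, 354 and 904. A pseudocount of 0.1 gave 926, 999, 979, 1236, 678 and 1664, because it counts smaller differences at low FPKM. TPM gave 1566, 1677, 1666, 2004, 1320 and 2783, because TPM values are higher than FPKM and the pseudocount of 1 weighs less. For combination against DC vaccine TPM gave 801 higher and 1203 lower genes beside 211 and 511, for combination against PBS 847 and 819 beside 210 and 298, and for combination against Tara 705 and 615 beside 174 and 180. A floor of 5 FPKM gave 162, 191, 206, 305, 78 and 299, and a size of 1.5 gave 158, 156, 153, 253, 107 and 317, since both count fewer genes. Genes shared by Tara and the combination numbered 248, with a pseudocount of 0.1 474 and with a size of 1.5 85. In the same order the numbers were 146, 313 and 29 for the DC vaccine and the combination, and 129, 276 and 28 for Tara and the DC vaccine. The correlation of the taraxasterol differences was 0.306, and 0.207 without genes that followed the muscle list and 0.204 with a pseudocount of 0.1; the filter lowers it by construction. That of the vaccine differences was 0.0472, and 0.0720 and 0.0312 in the same order. With a pseudocount of 0.1 the libraries separated 298 genes by taraxasterol, 102 by vaccine and 85 in the remaining split, in place of 99, 28 and 19. Among gene lists, with each median counted once per alternative setting, 906 stayed on the same side of the central 95% of random lists, 25 moved inside it and 28 outside. The median of macrophage genes of alternative activation in the DC vaccine library against PBS went from -0.18 to 0.043 with members of at least 5 FPKM, so that list has no stable direction; fewer members were used there. The differences of named genes were counted once per alternative setting too. Of these, 1756 moved by no more than their counting error (by no more than 1 where no interval exists) and 137 moved by more, and no difference of 1 or more turned its direction. Several columns per group, and leaving out replicates, had been planned for a table with replicates and were not run, since each group had 1 column. Depth limits genes with few reads, such as the small RNAs, some of whose intervals held a ratio of 1.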

Other observations

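This part gives genes picked after their values had been seen, and its test was chosen after the result. Several genes separated the libraries by taraxasterol with little regard to the vaccine. Kank3 had 8.26 FPKM in PBS, 7.00 in the DC vaccine library, 15.2 in Tara and 16.1 in the combination, and Cbr2, a carbonyl reductase, had 17.8, 17.7, 39.5 and 29.8. Serping1, the C1 inhibitor, had 11.2 and 13.5 FPKM in the libraries without taraxasterol (PBS and DC vaccine) and 2.05 and 2.25 in those with it (Tara and combination). The imprinted RNA H19 had 7.38 and 11.8 against 0.993 and 1.23 in the same order.

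Other genes separated the libraries by vaccine. Padi4, a peptidylarginine deiminase, had 6.85 FPKM in PBS and 5.40 in Tara against 16.3 in the DC vaccine library and 14.0 in the combination. Prph, an intermediate filament protein of neurons, had 27.5 and 25.3 against 53.4 and 47.2, and the eosinophil chemokine Ccl11 had 3.60 and 4.52 against 9.22 and 7.86. Lyve1, a marker of lymphatic vessels and of some macrophages, had 5.38 and 5.45 against 1.46 and 2.81.

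The 4 libraries can be split into 2 and 2 in 3 ways. Splitting by taraxasterol separated 99 genes by a gap of at least 1 on the log2(FPKM + 1) scale (15 higher and 84 lower with taraxasterol), splitting by vaccine 28, and setting the single treatments against the other 2 libraries 19. Of the genes named above in this part, only Serping1 and H19 had a gap of at least 1, and the others had smaller gaps. If the libraries were interchangeable, each split would separate about 33.3% of the genes, and the shares were 40.7%, 32.1% and 26.4%. The order of the 3 splits is consistent with taraxasterol acting alike with and without the vaccine, but any 1 of 3 splits would come first by chance, and tissue content such as muscle and blood differed along the same split (Atp2a1, Acta1 and Myh4 are among its lower genes), so this stays a hypothesis.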
